A study of Anser cygnoides with 12 samples.

How the data were processed

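Poly(A)-selected RNA from breast (pectoral) muscle of Xingguo grey geese, a Chinese goose breed of the species Anser cygnoides, was sequenced in 12 libraries. Per the labels, 5 libraries came from muscle with high intramuscular fat (high_IMF) and 7 from muscle with low intramuscular fat (low_IMF). Intramuscular fat is the fat stored within a muscle. Libraries are named here as in the sample titles, whose leading letters (M in all 5 high_IMF and F in all 7 low_IMF libraries) follow the groups and are not explained by the labels. The labels do not say whether each library is a separate bird, so the p-values measure the spread between these samples.

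The deposited values were raw counts per gene model, one table for all libraries, whole numbers with no normalization. HISAT2 and DESeq2 are named in the submitters' processing notes, with no version or role. The counting program, the genome build, the annotation and the strand setting were not given in the sources used here. Reads of models that overlap, lie antisense to each other or share sequence with a copy can therefore not be told apart. Total counts per library ran from 13481727 to 18458606, and all 12 columns of the table were used.

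The table held 23065 gene models. Their IDs place 15301 models on 39 chromosomes and 2267 on 804 contigs, and 5497 IDs carry the word newGene with no position. Chromosome numbers below are those in the IDs and belong to an assembly that was not named, so no base coordinates are given. The files do not pair the IDs with gene names, and 0 of the 23065 IDs matched the reference gene table, which belongs to a Taihu goose assembly. The 32 gene lists (944 genes) and the 29 key genes fixed before the data were examined, for muscle, fat, other cell types and the Z chromosome, therefore matched 0 IDs. Their set tests, per-library scores and sex-chromosome check were not run. The planned rule for named genes required a gene symbol. Without symbols it was reduced to the 2 highest and the 2 lowest log2 fold changes among models with an adjusted p under 0.05 and a mean of at least 1 CPM (counts scaled by the library total times its TMM factor).

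Counts were filtered with filterByExpr at its defaults, scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with the Benjamini-Hochberg adjustment over all 14031 models tested and a threshold of 0.05. Fold changes are high_IMF over low_IMF, and their standard errors were derived from the F statistic. Per-library measures were compared by an exact two-sided permutation test over all 792 splits of the 12 libraries into 5 and 7, whose smallest p is 0.00126. For a model with 0 counts in a group, a fold was bounded with a floor of 3 counts over the group. The number of models at 1 CPM or more per library used the total counts without the TMM factor. Shares of single libraries have Wilson 95% intervals at most 0.0518 points wide. The labels describe no molecular identifiers, so intervals and floors cover counting error only.

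Further summaries used the order of the models. Chromosome medians were taken over models with a mean log2 CPM of at least 2 (prior count 2). Each model's deviation from its mean over the libraries was computed, and the library's median over all such models was subtracted, for each chromosome with at least 20 models, for contigs together and for newGene models. These 40 sequence groups were also tested with camera (limma 3.58.1, preset correlation 0.01). Models with consecutive numbers on a sequence were paired, and the correlation of their fold changes was compared with 1000 shuffles of the values within sequences. Both summaries were chosen after the data were seen. The plan fixed before that did not hold the tests of direction on contig and newGene models or the abundance bins. It also did not hold the count of models seen only in low_IMF, the number of models at 1 CPM or the comparison of TMM factors. Their p-values are those of unplanned tests.

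The main test was tested on simulated data drawn from these libraries' means and sizes for 14031 models, with 50 models changed at each fold size. It recovered 2% of the 1.5-fold changes, 24% of the 2-fold, 78% of the 4-fold and 98% of the 8-fold. Of 108 simulated calls, 7 were false (6.48%). Far fewer models were changed in the simulation than passed in the real comparison (2525). The adjustment is stricter when few models change, so the recovered shares can understate those of the real test. No pair of libraries agreed within sampling noise, as the lowest chi-square per model over the 66 pairs was 35.0.

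Alternatives fixed before the data were examined were median-ratio and upper-quartile scaling, other count filters, DESeq2 1.42.0, limma-voom with and without quality weights, robust dispersion, a surrogate variable (sva 3.50.0), a replicate block over shared library numbers, stricter thresholds, library sizes without the 10 most abundant models, and each library left out in turn. Alternatives added after seeing the data left out M001 and M0011, F001 and F009, or the models of chr12 and chr23, or took the contig median as a covariate. The alternatives for chromosome medians, classes, abundance bins, neighbours and models seen only in low_IMF were also added then.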

Results

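The libraries compared breast muscle of Xingguo grey geese with high and with low intramuscular fat, to find which transcripts differ in level between them. The high_IMF group held 5 libraries and the low_IMF group 7. Total counts per library ran from 14623374 to 18458606 in high_IMF and from 13481727 to 17750379 in low_IMF, and the group means differed by less than the spread between libraries (exact permutation p = 0.612).

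Of 14031 gene models tested, 2525 differed between high and low intramuscular fat at an adjusted p under 0.05 in edgeR. Of these, 1188 were higher and 1337 were lower in high_IMF muscle. The median log2 fold change was 0.95 among the higher and -1.11 among the lower models. At least 2-fold changes were seen for 534 of the higher and 779 of the lower models, and at least 4-fold changes for 57 and 172. The 5 high_IMF libraries did not overlap the 7 low_IMF libraries for 1094 models (7.80%), where chance gives 0.253%, and 1037 of these were among the 2525. The first principal component, with 28.1% of the variance, placed all high_IMF libraries on one side of all low_IMF libraries, and the second component (18.4%) did not part the groups. The balance of the directions depended on the scaling, as median-ratio scaling gave 1326 higher and 1242 lower. DESeq2, which also scales by median ratios, gave 1716 higher and 1677 lower, and limma-voom on TMM scaling 1102 higher and 1292 lower. Without M001 and M0011, in which a few models took over 50% of the counts, 1579 models passed (596 higher, 983 lower), 1251 of them among the 2525. Without M0011 alone 725 were higher, and without F001 and F009, which stood apart on chr12 and chr23 once the contig median was regressed out, 1430 passed (574 higher, 856 lower), 1382 of them among the 2525.

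**Figure D1:**
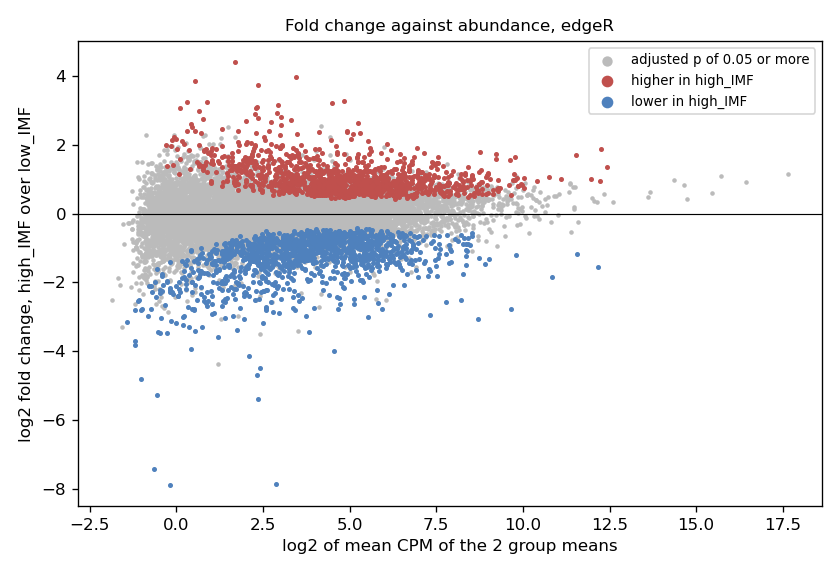
Each point is 1 of the 14031 gene models tested, with the log2 of its mean CPM over the 2 group means on the x axis and its log2 fold change, high_IMF over low_IMF, on the y axis. The 1188 models higher in high_IMF are red and the 1337 lower ones blue (edgeR, adjusted p under 0.05), and the lowest points have 0 or nearly 0 counts in high_IMF, where the fitted fold is no bound.

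Direction went with abundance in most fits when the tested models were ranked by mean CPM into 4 bins of 3507 or 3508. In the least abundant bin, 91 models were higher and 192 lower in high_IMF, so that 32.2% of the changed models were higher. This share was 40.9% in the next bin, 45.0% in the one after it and 56.8% in the most abundant bin, where 542 were higher and 412 lower. The share of models that changed at all went from 8.07% in the least abundant bin to 27.2% in the most abundant. Among the 50 most abundant models, 8 were higher and 3 lower. None of the 10 most abundant models passed the threshold, with edgeR adjusted p from 0.0558 to 0.358 and log2 fold changes from 0.34 to 1.15. Without M001 and M0011, the share higher among changed models was 29.4%, 38.0%, 37.5% and 39.8% from the least to the most abundant bin. Without F001 and F009 it was 34.9%, 39.1%, 38.0% and 43.8%, so the rise across the upper 3 bins was smaller without either pair of libraries. Without M0011 alone, the share in the most abundant bin was 47.3%, so that more of its changed models were lower than higher. limma-voom with quality weights gave 44.2%, 41.1%, 43.5% and 55.2%, with the least abundant bin above the next 2.

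Models placed on contigs and on chromosomes differed in direction when all libraries were used. Of 1011 contig models tested, 124 were higher and 79 lower in high_IMF, against 884 higher and 1004 lower of 10611 chromosome models. Among changed models, the odds of being higher were 1.78 times as large on contigs (95% interval 1.31 to 2.43, Fisher's exact test p = 1.16e-04). Tested as a group, the contig models did not pass with camera (adjusted p = 0.858 at the preset correlation and 0.955 at the estimated one of 0.138) or in the medians of 738 of them (exact permutation p = 0.244). Among 2409 newGene models, 180 were higher and 254 lower, with odds of 0.805 against the chromosomes (0.647 to 0.999, Fisher's exact test p = 0.0480). As a group they did not pass with camera either (adjusted p = 0.916 at the preset correlation and 0.955 at the estimated one). The contig result was lost without several libraries, with an odds ratio of 1.00 without M001 (Fisher's exact test p = 1), 1.34 without M0011 (p = 0.144), 1.34 without F0010 (p = 0.0607), 0.707 without M001 and M0011 (p = 0.154), 1.07 without F001 and F009 (p = 0.829) and 0.805 with the contig median as a covariate (p = 0.121). Over the 12 fits with 1 library left out, the odds ratio of newGene models ran from 0.717 (without M0035) to 1.09 (without M0011, Fisher's exact test p = 0.526). The newGene result was lost in 6 of these 12 fits (M0011, M0027, F001, F006, F0010 or F0013). It was also lost without M001 and M0011 (1.00, Fisher's exact test p = 1), without F001 and F009 (0.861, p = 0.308) and with the contig covariate (0.919, p = 0.410). With all libraries it was lost with no low-count filter (0.822, Fisher's exact test p = 0.0958), the CPM filter (0.814, p = 0.0617), limma-voom (0.832, p = 0.0987), limma-voom with quality weights (1.06, p = 0.543), robust dispersion (0.812, p = 0.0549) and a surrogate variable (0.884, p = 0.186). These tests count models, which are not independent replicates.

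Of the models that passed, evm.model.chr22.367.g, on the sequence named chr22 in the IDs, had the highest log2 fold change. It stood at 6.19 ± 1.497 CPM (SD, n = 5) in high_IMF and 0.278 ± 0.252 CPM (SD, n = 7) in low_IMF, a log2 fold change of 4.40 (SE 0.51, edgeR adjusted p = 2.04e-04). Its counts ran from 53 to 148 in the 5 high_IMF libraries and from 0 to 18 in the 7 low_IMF libraries. Anser_cygnoides_newGene_8928 was second, with a log2 fold change of 3.96 (SE 0.98, edgeR adjusted p = 0.0141). That value rested on M0027, which held 1157 of its counts, while the other high_IMF libraries held 6 to 140 and the low_IMF libraries 2 to 51. Without M0027 its log2 fold change was 2.16 and its edgeR adjusted p 0.0846.

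On the low side, evm.model.chr14.1064.g had 0 counts in all 5 high_IMF libraries and 3 to 89 counts in each low_IMF library. At 1.77 ± 1.65 CPM (SD, n = 7) in low_IMF it was at least 41.7-fold lower in high_IMF, measured against a floor of 3 counts over the group (edgeR adjusted p = 0.00528). This bound takes the low_IMF mean as it stands and does not cover the spread between libraries. Anser_cygnoides_newGene_4799 had 4 counts in M0035 and 0 in the other 4 high_IMF libraries. In low_IMF it had 0 counts in F001 and F006, 10 in F009 and 284 to 905 in the other 4 libraries (log2 fold change -7.85, SE 1.83, edgeR adjusted p = 0.0106). The zero counts in F001 and F006 lie within the range of the high_IMF libraries, so the groups overlap for this model. Its log2 fold change was -5.38 with limma-voom and -10.95 without M0035, where no high_IMF count is left and the fitted fold is no bound. It did not pass without M001 and M0011 (-7.38, edgeR adjusted p = 0.0602). limma-voom did not call Anser_cygnoides_newGene_8928 (adjusted p = 0.242, range over alternatives 0.00223 to 0.419) or Anser_cygnoides_newGene_4799 (adjusted p = 0.460, range 0.00278 to 0.520). With quality weights it did not call evm.model.chr14.1064.g either (adjusted p = 0.0509, range 3.14e-07 to 0.156).

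Over all 23065 models, 8 had at least 1 count in each of the 7 low_IMF libraries and 0 counts in all 5 high_IMF libraries. The reverse was seen for 0 models, which is also its median over all splits, so that 0 is no contrast. For the 8 models seen only in low_IMF, the other splits were compared, in a test that was not planned before the data were examined. No other of the 792 splits of the libraries gave as many as 8, and the highest other count was 7 (one-sided exact permutation p = 0.00126, the smallest this design can give). These models were scarce, with means of 2.29 to 32.3 counts per low_IMF library. Scarce models could also reach 0 counts more easily in M001 and M0011, which had the lowest TMM factors (0.499 and 0.682). Of the 8, 2 were abundant enough to be tested. Both passed, which models picked for not overlapping between groups would tend to do. Leaving out a library can only raise the count, and it was 23 without M006, 16 without F0010, 15 without M0011 and 13 without M0027.

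Models next to each other moved together. Fold changes of models with consecutive numbers on a sequence correlated with r = 0.299 over 5590 pairs, where 1000 shuffles within sequences gave a mean of 0.0295 and at most 0.0687 (one-sided permutation p = 0.000999, the smallest these shuffles can give). With the fold changes of DESeq2, which included more scarce models, r was 0.166. In edgeR the correlation was 0.121 at a gap of 2 models, 0.0904 at 3, 0.0582 at 5, 0.0619 at 10 and -0.0329 at 50. Both models of 233 consecutive pairs changed in the same direction, against 98.6 on average and at most 133 in the shuffles. In 49 pairs they changed in opposite directions, against 85.5 on average and at least 55 in the shuffles. The correlation is across models of one comparison, and neighbouring models can be parts of one gene or share reads.

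The most abundant transcripts took a larger share of some high_IMF libraries. The 10 most abundant models of each library held 48.6% ± 11.4 (SD, n = 5) of the counts in high_IMF and 39.1% ± 4.19 (SD, n = 7) in low_IMF, a difference of 9.45 points that did not pass the test (exact permutation p = 0.0505, adjusted p = 0.135 over 8 measures). M001 reached 66.0% and M0011 54.4%, while the other 3 high_IMF libraries lay between 39.5% and 41.8%, within the low_IMF range of 32.1% to 44.7%. A single newGene model, the most abundant one, held from 9.04% of the counts in F0013 to 32.8% in M001. Fewer models reached 1 CPM of the total counts in high_IMF, 12255 ± 681 (SD, n = 5) against 13015 ± 248 (SD, n = 7), with an exact permutation p of 0.0114 (adjusted p = 0.0455). With CPM scaled by TMM, an alternative chosen after seeing the data, the numbers were 12638 ± 174 (SD, n = 5) and 12778 ± 159 (SD, n = 7), and the difference did not pass (exact permutation p = 0.192). The TMM factor, which offsets such composition, was 0.861 ± 0.257 (SD, n = 5) against 1.15 ± 0.0958 (SD, n = 7), with an exact permutation p of 0.00505 (adjusted p = 0.0404). Leaving out M001 and M0011 brought the difference in the top-10 share to 1.69 points (exact permutation p = 0.533), and leaving out M001 alone brought it to 5.10 points (exact permutation p = 0.164). Its exact permutation p fell under 0.05 without M006 (0.0424), M0027 (0.0273), M0035 (0.0394), F001 (0.0498) or F006 (0.0281).

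**Figure D2:**
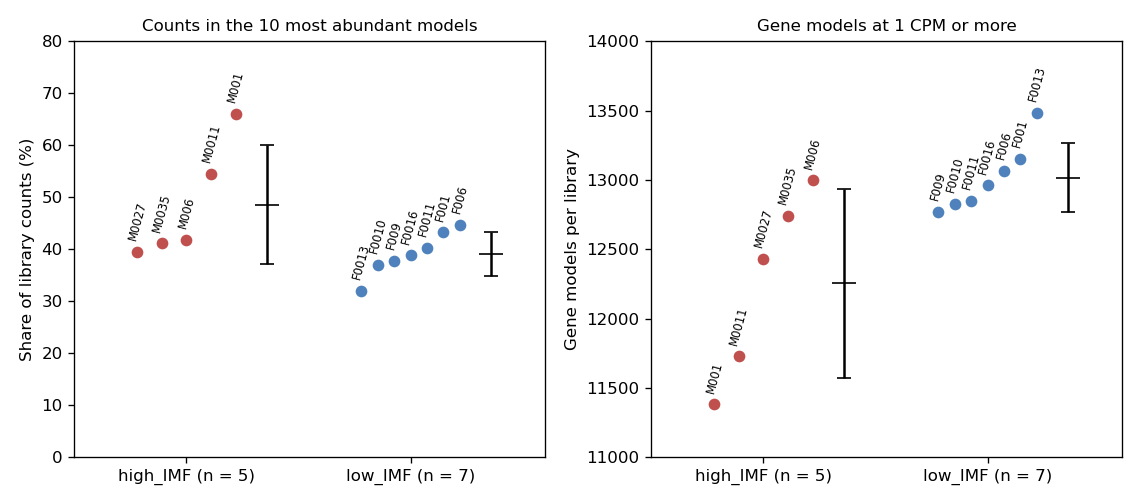
The left panel plots the share of each library's counts in its 10 most abundant models (%), and the right panel the number of gene models at 1 CPM of the total counts or more, with 1 point per library and bars for the mean and SD of each group (the right axis does not start at 0). M001 and M0011 have the highest shares (66.0% and 54.4%) and the fewest models (11382 and 11728).

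Group differences in the medians of whole chromosomes were small. Of 40 sequence groups (38 chromosomes, the contigs and the newGene models), 4 had an unadjusted exact permutation p under 0.05 and 0 an adjusted one. A single group could not go below an adjusted p of 0.0505 in this exact test, so that count does not show that chromosomes did not differ. With camera 0 passed and 1 had an unadjusted p under 0.05, and an estimated correlation also gave 0 calls. The difference in chromosome medians reached its largest size on chr25, whose 257 models stood at a log2 deviation of 0.08 ± 0.05 (SD, n = 5) in high_IMF and -0.06 ± 0.03 (SD, n = 7) in low_IMF. Its libraries did not overlap between groups, and its exact permutation p was 0.00126 (adjusted p = 0.0505), both the smallest possible for a single group. With the contig median regressed out of the chromosome medians, an alternative chosen after seeing the data, chr25 (0.11) and chr38 (-0.21, 31 models) passed (exact permutation adjusted p = 0.0246 for each). Before that step chr38 differed by -0.06, with overlapping libraries (exact permutation p = 0.715, adjusted p = 0.841). Without F0011, chr25 (0.13) and chr24 (0.07) passed (exact permutation adjusted p = 0.0433 for each).

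**Figure D3:**
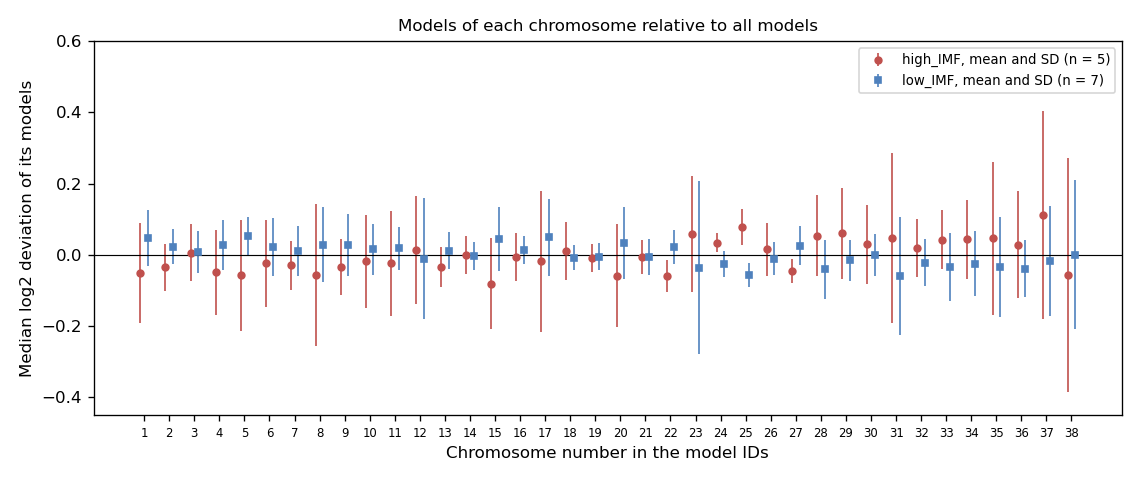
For each of the 38 chromosomes with at least 20 models, by its number in the model IDs on the x axis, points and bars give the mean and SD over libraries of the median log2 deviation of its models, in 5 high_IMF libraries (red) and 7 low_IMF libraries (blue). On chr25 the groups lie apart (0.08 and -0.06), and on chr12 and chr23 the spread within groups is wider than the difference between them.

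Single libraries differed more on some sequences than the groups did. The median log2 deviation of the 738 contig models ran from -0.44 in F0010 to 0.54 in M001, and that of chr37 from -0.30 to 0.51 in the same libraries. The groups did not differ in the contig median past the threshold (difference 0.19, exact permutation p = 0.244, adjusted p = 0.609). On chr12 the median was -0.25 in F001, -0.22 in M001 and -0.14 in F009, so F009 did not stand apart there before the contig median was regressed out. On chr23 it was -0.41 in F001, -0.31 in F009 and -0.18 in M001, the next lowest. After that step, chr12 stood at -0.28 in F001 and -0.21 in F009, with the lowest of the other 10 libraries at -0.05. On chr23 the values were -0.43 and -0.37, with the lowest of the other 10 at -0.04.

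**Figure D4:**
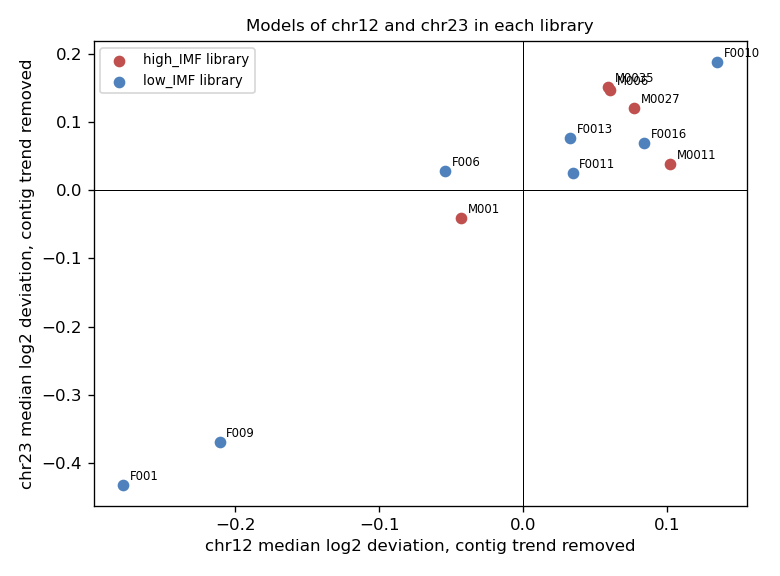
Each point is 1 library, with the median log2 deviation of its chr12 models on the x axis and of its chr23 models on the y axis, after the trend with the contig median was regressed out (red high_IMF, blue low_IMF). F001 (-0.28, -0.43) and F009 (-0.21, -0.37) lie below the other 10 libraries on both axes.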

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

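Of 31 groups of per-library values, 5 held a library far from the rest of its group by Dixon's test, where chance flags about 1 in 20. That rate is only a rough guide, because the values included named models picked for extreme fold changes and the chr12 and chr23 medians. F0013 stood apart in low_IMF on 3 related measures. The 3 models most abundant over all libraries held 15.5% of its counts, where the next lowest low_IMF library had 23.9%. Its newGene models held 30.2% of the counts where the next lowest had 37.3%. Its TMM factor was 1.36 where the next highest was 1.15. Anser_cygnoides_newGene_8928 stood at 78.2 CPM in M0027, where the next high_IMF library had 11.1 CPM. Anser_cygnoides_newGene_4799 stood at 0.257 CPM in M0035 and at 0 in the other 4 high_IMF libraries, a difference of 4 counts. With 0 in those 4, any count in M0035 would have been flagged.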

How the results depend on the processing

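Settings that left out 2 libraries, took the contig median as a covariate or refitted the 6 libraries without a block were chosen after seeing the data, as were those for chromosome medians, classes, neighbours and models seen only in low_IMF. Of the 2525 calls, 0 changed sign in any of the 28 other fits. A surrogate variable gave 3732 calls (2510 of the 2525 among them), median-ratio scaling 2568 (2430) and DESeq2 3393 (2523). Without M001 and M0011, 1579 passed (596 higher, 983 lower; 49.5% of the 2525 kept), and without F001 and F009, 1430 (574 higher, 856 lower; 54.7% kept). An adjusted p under 0.01 left 776 (271 higher, 505 lower), and a 2-fold minimum left 1313 (534 higher, 779 lower). With each library left out, 1696 to 2628 passed, with 725 (without M0011) to 1267 higher and 971 to 1428 lower.

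The library numbers shared by the groups (001, 006 and 0011) did not pair the samples, as the correlations of their deviations were 0.000164, -0.124 and 0.114 and no high_IMF library correlated best with its own number. With these numbers as a replicate block over 6 libraries, 13 models passed (5 higher, 8 lower), and the same 6 libraries without the block gave 22 (4 higher, 18 lower), so most of the loss came with fewer samples. The tests on gene lists, key genes and Z- or W-linked genes, and the fit without Z- and W-linked genes, were not run because no ID could be joined to a name.

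The difference in the top-10 share was 9.13 points for the top 50 (exact permutation p = 0.0278) and 5.10 to 11.7 points with each library left out. Models at 1 CPM and the TMM factor kept an unadjusted exact permutation p under 0.05 without each library, but with CPM scaled by TMM the difference in models at 1 CPM was -140.1 (p = 0.192). The count of models seen in each low_IMF library and no high_IMF library ran from 9 to 23 with each library left out. The sequence groups that passed numbered 2 with the contig median regressed out and 0 to 2 with each library left out (2 without F0011). There a single group could not go below an adjusted p of 0.121 (without a high_IMF library) or 0.0866 (without a low_IMF library), so a count of 0 says nothing. The odds ratio for contig models turned to 0.707 without M001 and M0011 and 0.805 with the contig covariate (9 of 12 fits with 1 library left out kept it). That for newGene models turned to 1.00 without M001 and M0011 and 1.06 with limma-voom and quality weights, and ran from 0.717 to 1.09 with each library left out (6 of 12 kept it). The neighbour correlation was 0.166 to 0.311 in 19 fits, lowest with DESeq2. Of the named models, evm.model.chr22.367.g passed in all 28 fits, Anser_cygnoides_newGene_8928 in 23 of 28, evm.model.chr14.1064.g in 24 of 27 and Anser_cygnoides_newGene_4799 in 16 of 19 that tested it. Simulated data at this depth and spread, with far fewer models changed than the 2525 that passed here, recovered 2% of 1.5-fold changes. Depth was not varied.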

Other observations

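Of the tests in this part, the one on other splits of the libraries was set before the data were examined, and the others, the scan of chromosomes for sex included, were chosen only after the result was seen. The chr23 models of F001 and F009 were lower as a body, while on chr12 this was not shown for F009. On chr23, 76.9% of 117 models in F001 and 74.4% in F009 lay below their median over the 12 libraries, and on chr12, 72.1% and 60.6% of 251 models did. For these percentages, the library's median deviation over all such models was first subtracted from each model, and the contig trend was not removed. On the other 36 chromosomes this percentage was at most 58.1% in F001 and 70% in F009 (on chr37). F001 and F009 were the lowest pair of libraries on chr12 and chr23 and on no other of the 38 chromosomes once the contig median was regressed out.

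On chr23 the values argue against the contig trend and against a few changed models. After the contig trend was regressed out, a gap of -0.33 (log2) to the lowest of the other 10 libraries remained there. A few strongly changed models cannot give 74.4% of models below the median. The 2 libraries and the chromosome were picked from these same medians, so both values describe the pattern and are not independent evidence for it. On chr12 a few changed models stay open, since the 60.6% in F009 lies under the 70% that F009 reached on chr37. A candidate explanation is a single copy of a chromosome, as of Z in female birds, if chr12 and chr23 belong to one sex chromosome, an assumption the IDs cannot settle. Models with at least 5 counts in both libraries of a pair and at most 1 in each other library were counted over 66 pairs. F001 and F009 shared the most, as W-linked models would give, but only 11 against 8 in the next pair. Of the 11, 3 were on chr12 and 0 on chr23, and under that assumption models on chr12 would not be W-linked. A complete split of the groups by sex, taken up below, could not hold together with W-linked models in F001 and F009 only. An uneven share of the sexes between the groups could. The labels name neither sex nor the sex chromosomes, so the single-copy explanation stays open.

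Chance alone is an unlikely source of the count of 2525 models. In 100 splits of the 12 libraries drawn with the real one, 1 split, the real one, gave as many. The highest of the others gave 1 model. Each other split mixes high_IMF and low_IMF libraries, so a group difference of any cause widens its spread and lowers its calls. The labels also do not say whether the libraries are separate birds, so chance is not excluded. The values argue against 2 libraries with dominant models, or the contig trend, as the whole cause of the count. Without M001 and M0011, 1579 models still passed (596 of them higher), but only 49.5% of the 2525 were kept. With the contig median as a covariate, 3169 passed (87.7% of the 2525 kept). The fold changes of the 2525 models had median ratios to the main fit of 0.952 without these libraries and 0.970 with the covariate. These models were picked with all libraries, which favours ratios near 1, so the ratios alone do not decide. A difference in sex between the groups could add to the count and cannot be told apart from fat content here, because no ID is tied to Z or W and the unexplained letters of the library names (M in all 5 high_IMF, F in all 7 low_IMF) coincide with the groups. Of the 39 chromosomes in the IDs, 38 were scored, and 0 combined a group difference of at least 0.2 (log2) with no overlap of the libraries. After the contig median was regressed out 1 did, chr38 with 31 models (-0.21, against -0.06 with overlap before). Its lower side is high_IMF, while the 8 models seen only in low_IMF would as W-linked models need low_IMF to be the lower side. The bound of 0.2 for a sex difference on Z was assumed. Z may also lie on contigs, among newGene models or on the unscored chromosome, so neither count decides on sex. Age, rearing and batch are not given in the labels and stay untested.

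Contig models and those of chr31, chr35 and chr37 rose or fell together in single libraries. The contig median correlated with the share of counts in the 10 most abundant models (Pearson r = 0.777, permutation p = 0.00272, adjusted p = 0.00816; Spearman rho = 0.664, permutation p = 0.0215, adjusted p = 0.0646, over 3 relations and 12 libraries). Without M001 and M0011, the libraries farthest from the median share, r was 0.240 (permutation p = 0.510), so the relation rests on those libraries. The newGene share of counts gave r = 0.658 (permutation p = 0.0231, adjusted p = 0.0346) and rho = 0.406 (permutation p = 0.191). Without M001 and M0011 its r was -0.154 (permutation p = 0.683). Total counts gave r = 0.488 (permutation p = 0.108; rho = 0.385, p = 0.218), or 0.0767 without F0010 and M0011, and fat group gave an exact permutation p of 0.244. A few dominant models, library size and fat group may each contribute, and 12 libraries do not decide between them, while GC content was not tested because the sequence of the models was not used here.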
